A study of Homo sapiens with 14 samples.

How the data were processed

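RNA of epidermal organoids grown from N/TERT-2G keratinocytes was measured in 14 libraries of 5 lines, WT, a polyclonal hFWE knockout pool and knockout clones 5, 8 and 11. Per the labels' protocols, cells were kept submerged for 72 hours and then exposed to air, total RNA was isolated after 10 days at the interface, and 500 ng went into a directional poly(A) library kit. The deposited table holds 1 value per gene and library on a variance-stabilised log2 scale. Trim Galore, STAR, Salmon, DESeq2 and the genome build GRCh38 are named in the submitters' processing notes, without versions or roles. The annotation release, any filter, the settings of the transformation and whether counting used the strand of the reads are not given in the sources used here. Reads of overlapping antisense genes and of near-identical copies could therefore be split between genes, and such genes are named as uncertain.

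The lowest value of the table, 5.56, occurs in every library and was taken as a count of 0. Inverting the transformation at that value gave normalised counts, whose totals were 18195773 to 20825517 per library. Low values fell on steps, and the size of a step gave an estimated depth of about 16133772 to 22398135 reads per library. Between 73.0% and 80.2% of low values lay within 0.1 of a whole step, so whole reads were not recovered and no count model was used. The 10 most abundant genes took 12.7% to 15.9% of the total. The transformation compresses differences of genes with few reads, so a log2 difference understates their fold change.

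Of 24094 gene identifiers, 23896 had a symbol in the name table and 22571 a position and biotype in GENCODE release 29 (GRCh38), which may not be the release the authors used. Genes whose mean over all libraries was at least 1 above the lowest value were tested, 12835 in all. The values were fitted with limma 3.58.1 in R 4.3.3, with 5 group means in 1 fit over the 14 libraries and a mean-variance trend, and a gene was called at a 2-sided Benjamini-Hochberg adjusted p under 0.05. The model shares its estimate of the spread because each line has only 2 or 3 libraries. Contrasts were each KO line against WT, the mean of the 4 KO lines and of the 3 clones against WT, the clones against each other, the pool against the mean of the clones, and each line against the mean of the other 4. A gene counted as shared when it passed with the same sign in each of the 4 KO lines. Unchanged lines that share the WT libraries were simulated 20 times to see the overlap they give.

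Lists of genes, 37 in all, covered epidermal layers, barrier lipids, stress and signalling pathways, markers of other cell types and signs of RNA quality. They were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. The camera test with a correlation estimated per list and the fry test, which asks whether the genes of a list move one way on balance and does not compare them with other genes, were alternatives, and a call that either ended is given with that adjusted p. With an estimated correlation the interferon-stimulated genes kept their call in clone 8, in the mean of the clones and in the pool against the clones, and among the lists called for the mean of the KO lines, for a KO line, for the pool against the clones or between clones no other call held. Named genes were the target, the 10 largest rises and 10 largest falls shared by the 4 lines, and the 4 largest rises and falls of each line whose libraries all lay outside the range of WT. They also included the 3 largest rises and falls of each clone against the other 2 and of the pool against the clones, and up to 4 members of each described list with the smallest adjusted p. They were protein-coding genes with a symbol, and Y-linked genes were not eligible. Lists, contrasts, the naming rule and most alternatives were set before the data were examined. The comparison of chromosome 20, the neighbouring genes on 9p21 and 17q, IFNK, the log2 of a normalised count plus 1 and the count without chromosome 20 were chosen afterwards.

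The fit was tested on simulated data made from the 12835 tested genes, with 67 genes changed by 0.5, 67 by 1 and 66 by 2 on the log2 scale. For the comparisons of a KO line with WT it recovered 62.7% (clone 8) to 82.1% (clone 5) of changes of 0.5 and 98.5% to 100% of changes of 1, with 2.63% to 6.16% false calls. For the mean of the 4 KO lines it recovered 91.0% of changes of 0.5, with 7.02% false calls. The simulated noise was independent between genes and libraries, and each change was alike in all KO lines. These rates therefore leave out differences between lines that are not due to the knockout. Alternatives were no filter, a stricter filter of 3 above the lowest value, a limit of 1 on the log2 difference, quantile normalisation, median centring, no trend, a robust fit, library weights, the replicate number as a block, only the 2 groups compared, a 2-group fit, the line as a random block and each library left out in turn. Neither scaling shifted the median difference of all tested genes by more than 0.0265. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Raw reads and any measurement other than RNA were not used here.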

Results

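Knockout of hFWE, the human Flower gene, was examined for its effect on the differentiation and barrier function of epidermis. Flower is a multi-pass membrane protein encoded by CACFD1 and is known from flies as a protein of synaptic vesicles and of cell competition. N/TERT-2G is a line of human epidermal keratinocytes made immortal with telomerase. It stratifies and cornifies when it is lifted to the air-liquid interface. Wild-type cells, a polyclonal CRISPR-Cas9 knockout pool and 3 monoclonal knockout lines, clones 5, 8 and 11, were grown as epidermal organoids for 10 days at the interface and their polyadenylated RNA was sequenced. The 14 libraries comprised 3 each of WT, KO pool, KO clone 5 and KO clone 11 and 2 of KO clone 8. Estimated depth was about 16133772 to 22398135 reads per library, and 12835 of the 24094 genes in the table passed the expression filter. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries. Libraries of a line correlated across genes at r = 0.991 to 0.995, except in clone 11, whose libraries correlated at 0.973 to 0.991. Principal component 1 held 37.1% of the variance and set the KO pool and clone 5 apart from clone 11. Component 2 held 21.6% and set WT apart from clone 5.

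The target gene CACFD1 (ENSG00000160325.15, chromosome 9, 133459965 to 133470848, plus strand, GRCh38) was measured first. Its normalised count was 574 ± 59.8 (SD, n = 3) in WT, 337 ± 26.2 (SD, n = 3) in the KO pool, 637 ± 73 (SD, n = 3) in clone 5, 511 ± 43.3 (SD, n = 2) in clone 8 and 343 ± 104 (SD, n = 3) in clone 11. On the log2 scale it fell in the pool, with a difference of -0.64 ± 0.14 (SE, as for every log2 difference here; adjusted p = 0.0055, lower in 3 of 3 libraries), and in clone 11, with a difference of -0.65 ± 0.14 (adjusted p = 0.00397, 3 of 3). The differences in clone 5, 0.13 ± 0.14 (adjusted p = 0.573), and clone 8, -0.14 ± 0.16 (adjusted p = 0.64), did not pass the test. Clone 5 exceeded clone 11 by 0.78 ± 0.14 (adjusted p = 9.88e-04). The mean of the 4 KO lines lay -0.32 ± 0.11 from WT (adjusted p = 0.0572) and missed the threshold, which it passed without KO clone 11 replicate 3, at -0.37 (adjusted p = 0.00823), and without its replicate 1, at -0.28 (adjusted p = 0.025). It also passed with quantile normalisation, at -0.35 (adjusted p = 0.0418), with median centring, at -0.34 (adjusted p = 0.0454), and with library weights, at -0.24 (adjusted p = 0.0482). With those weights the fall in clone 11 no longer passed, at -0.48 (adjusted p = 0.0718). The weights did not converge and gave clone 11 replicate 2 a weight of 0.0019, so little rests on these 2 weighted values. The position of the edit was not used here and small insertions or deletions need not lower a transcript, so these levels neither check nor contradict the labels. Among the 12 measured neighbours of CACFD1 on 9q34, 2 rose and 1 fell in the mean of the KO lines, with a median of -0.06 (3 and 1 adjusted over the list alone; camera adjusted p = 0.817).

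**Figure D1:**
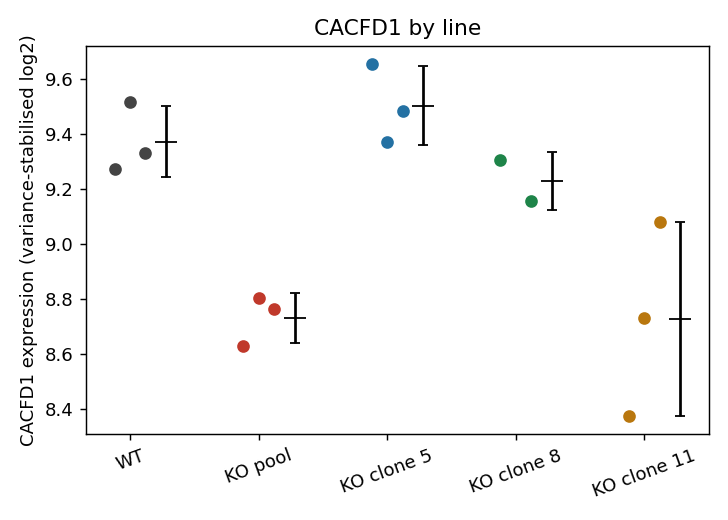
CACFD1 expression in variance-stabilised log2 units in each library (points), with the mean and SD of each line (bars). The pool libraries lie below every WT library, clone 5 overlaps WT, and clone 11 spreads from 8.37 to 9.08.

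The KO lines as a whole were compared with WT to find changes that accompany the knockout label. The largest rises shared by the lines included MMP9 and MMP2, the gelatinases, by 2.67 ± 0.26 and 1.61 ± 0.11 on the log2 scale, CSPG4, a membrane proteoglycan, by 2.13 ± 0.11, SPON2, a secreted matrix protein, by 1.88 ± 0.09, and NID1, nidogen of the basement membrane, by 1.61 ± 0.10. SFRP1, a secreted Wnt antagonist, rose by 1.77 ± 0.10, DPYSL4 by 1.68 ± 0.09, TLL2, a tolloid-like protease, by 1.66 ± 0.13, IGFBP6, which binds insulin-like growth factors, by 1.52 ± 0.10 and SGK2 by 1.51 ± 0.14. The genes that fell were METRNL, which encodes a secreted factor (-2.87 ± 0.10), HSPB8, a small heat shock protein (-2.76 ± 0.12), RHOBTB3 (-1.68 ± 0.09), SVIP (-1.67 ± 0.10), SLC16A6 (-1.63 ± 0.15), CRISPLD2 (-1.50 ± 0.12) and SYTL2, of vesicle trafficking (-1.49 ± 0.10). FCGR3B (-1.81), LGALS7B, a galectin-7 gene (-1.69), and PCDHGB4 (-1.62) also fell, but they have near-identical copies or overlapping neighbours and their values are uncertain. All 20 passed in each of the 4 lines, with every adjusted p for the mean at or below 7.00e-06. They were the largest of the 221 rises and 172 falls shared by the 4 lines. These SEs and p-values use the spread between libraries of a line and leave out the spread between lines. With the line as a random block METRNL had an adjusted p of 0.453, and other genes named below did not pass either.

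**Figure D2:**
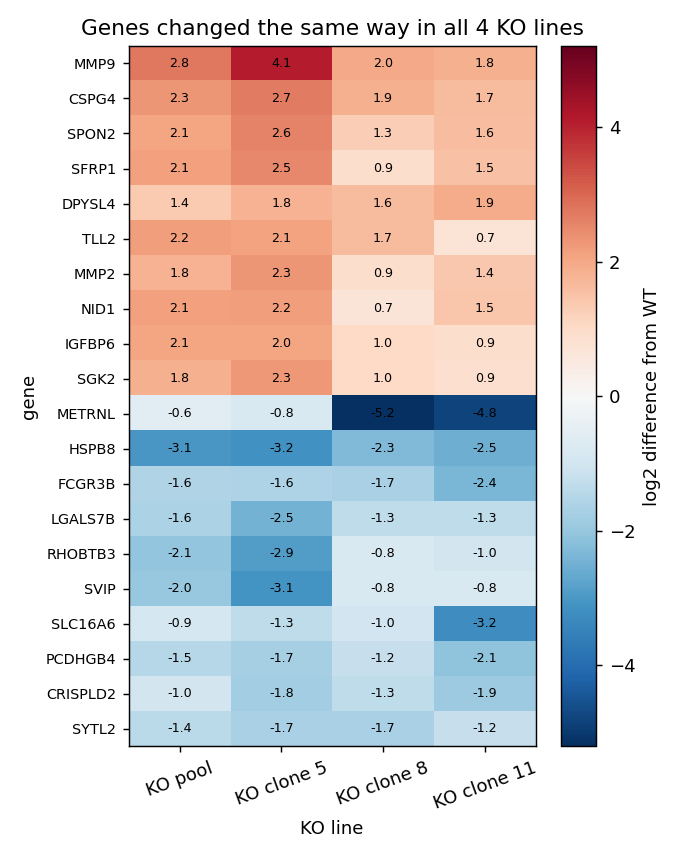
Log2 difference from WT of the 10 largest shared rises and 10 largest shared falls (gene axis) in each KO line (horizontal axis), coloured from blue (lower) to red (higher). HSPB8 lay between -3.16 and -2.29 in the 4 lines, whereas METRNL lay at -0.61 and -0.81 in the pool and clone 5 and at -5.21 and -4.84 in clones 8 and 11.

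In the mean of the 4 KO lines 1413 genes rose and 1229 fell, 50 and 61 of them by at least 1 on the log2 scale. Independent lists of the sizes seen in each line would share 1.17 rises and 0.635 falls, and simulated unchanged lines sharing the WT libraries gave 0 of each. Since no gene was changed in those simulated lines, few could pass in any of them. The 0 therefore does not measure how far shared WT libraries raise the overlap of lines with real changes. The WT libraries are too few to be split between the lines, so the overlap was not measured with separate controls. There is 1 WT line, so line and genotype cannot be told apart, and with the line as a random block 89 genes passed (47 up, 42 down), among which MMP9, TLL2, NID1, SGK2, METRNL, RHOBTB3, SVIP and SLC16A6 were not. A fit of all KO libraries against WT gave 867, without METRNL, SVIP and SLC16A6, and the count was 1653 without WT replicate 3, 1749 without WT replicate 1 and 1613 with the stricter filter. The 393 shared genes became 192 or 209 without either clone 8 library, 252 without WT replicate 3 and 243 with the stricter filter. Log2 differences of pairs of lines correlated across genes at r = 0.21 (pool and clone 11) to 0.76 (pool and clone 5), against 0.44 to 0.49 in simulated unchanged lines, and their covariance was 3.41 to 12.2 times the simulated one. Genes are not independent replicates. The mean of the 3 clones alone differed from WT in 1340 rises and 1217 falls, 1638 genes in all without WT replicate 3 and 1536 with the stricter filter.

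The shared changes were unevenly placed in the genome. Of the 172 shared falls, 35 lay on the short arm of chromosome 20, taken up to 25 Mb, where 103 genes were tested (2-sided Fisher's exact test, p = 1.36e-40). Of the 221 shared rises, 34 lay on its long arm, taken from 30 Mb, where 240 were tested (Fisher's exact test, p = 9.64e-22), MMP9 and SGK2 among them. The median difference of all tested short-arm genes was -0.38 in the pool, -0.39 in clone 5, -0.42 in clone 8 and -0.38 in clone 11, and that of the long-arm genes 0.21, 0.18, 0.24 and 0.26. Between clones 5 and 8 these medians differed by 0.01 and -0.06. This comparison was chosen after the data were examined, and the tests used the same genes that had prompted it. Fisher's exact test takes genes as independent, whereas the genes of an arm shifted together in each KO line. All KO lines were also compared with the same WT line. The p-values therefore overstate the evidence and do not measure replication. They only describe how unevenly the shared genes were placed.

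**Figure D3:**
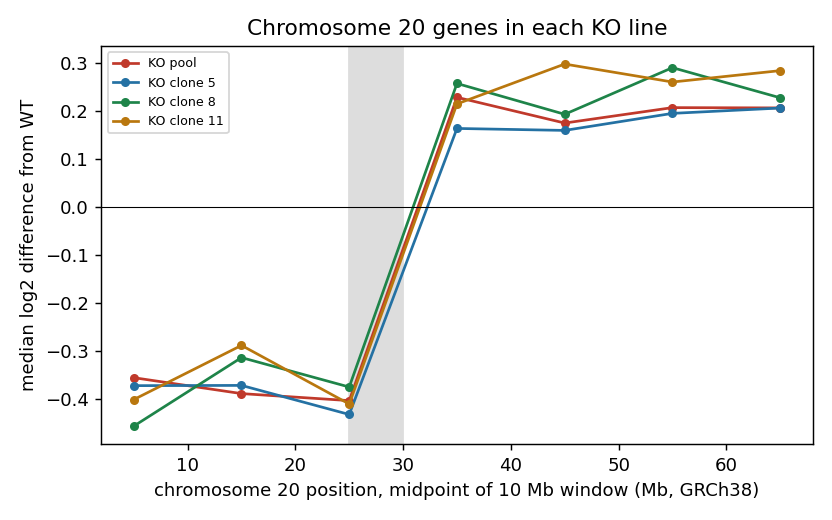
Median log2 difference from WT of tested genes in 10 Mb windows of chromosome 20 (horizontal axis, window midpoint in Mb, GRCh38) for each KO line. The grey band from 25 to 30 Mb was left out of both arms, and every window up to 30 Mb lies below 0 and every later window above 0 in all 4 lines.

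Gene lists fixed before the data were examined were tested next. Basal keratinocyte genes, of the proliferating layer on the basement membrane, were higher in the KO lines. In the mean of the lines 12 of 20 rose and 0 fell (15 rose adjusted over the list alone), with a median of 0.42 and rises of CAV1 by 0.53 ± 0.06, COL7A1 by 0.62 ± 0.10, ITGA3 by 0.43 ± 0.07 and DST by 0.67 ± 0.11 (camera adjusted p = 6.99e-08; adjusted p = 0.346 with an estimated correlation). Mesenchymal and wound genes had 9 rises and 2 falls among 24 (9 and 3 adjusted over the list alone), with TGFBI by 1.42 ± 0.09 and LOX, which crosslinks collagen, by 0.64 ± 0.10 beside the gelatinases (adjusted p = 0.00649, and 0.682 with an estimated correlation). Among 21 desquamation proteases and inhibitors 9 rose and 1 fell (the same counts adjusted over the list alone), led by the kallikreins KLK8 by 1.49 ± 0.14, KLK14 by 1.16 ± 0.12 and KLK11 by 1.18 ± 0.13 and by SPINK7 by 0.84 ± 0.12 (adjusted p = 0.0119, 0.139 with fry and 0.959 with an estimated correlation). Hypoxia and glycolysis genes had 9 falls and 1 rise among 30 (11 and 1 adjusted over the list alone). Falls were seen in PGK1, of glycolysis (-0.42 ± 0.05), EGLN3 (-0.89 ± 0.12) and BNIP3 (-0.67 ± 0.10), while ADM rose by 0.85 ± 0.12 (adjusted p = 0.00207, and 0.346 with an estimated correlation). The mean log2 difference of this list from WT was -0.24 in the pool, -0.30 in clone 5 and -0.19 in clone 11, but 0.05 in clone 8. Of 34 lysosome genes 6 fell, including ATP6V1A (-0.47 ± 0.06) and CTSB (-0.49 ± 0.07), and 1 rose (7 and 1 adjusted over the list alone). The camera adjusted p was 0.0266, with 0.117 after quantile normalisation and 0.346 with an estimated correlation. The mean log2 difference of the lysosome list from WT was -0.049 in the pool, -0.052 in clone 5, -0.087 in clone 8 and -0.177 in clone 11. Cytoplasmic ribosomal protein genes had 27 falls among 77 (40 adjusted over the list alone), with a median of -0.21 that was -0.14 after quantile normalisation (adjusted p = 1.33e-10, 0.0521 with fry and 0.9 with an estimated correlation). Their mean log2 difference from WT was -0.48 in the pool, -0.24 in clone 5 and -0.18 in clone 8, but 0.06 in clone 11. The 7 lists called for the mean, the 25 falls among 29 interferon-stimulated genes included (also 25 adjusted over the list alone; adjusted p = 0.206 with an estimated correlation), all lost the call with it. Cornified envelope, ceramide and barrier lipid, and barrier stress genes were not called as lists in the mean of the KO lines. Flower is known from flies as a calcium channel of vesicles that takes part in endocytosis. Calcium transport genes (2 up, 4 down of 27, also adjusted over the list alone, adjusted p = 0.559) and clathrin-mediated endocytosis genes (5 up, 4 down of 34, also adjusted over the list alone, adjusted p = 0.817) were not called as lists.

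**Figure D4:**
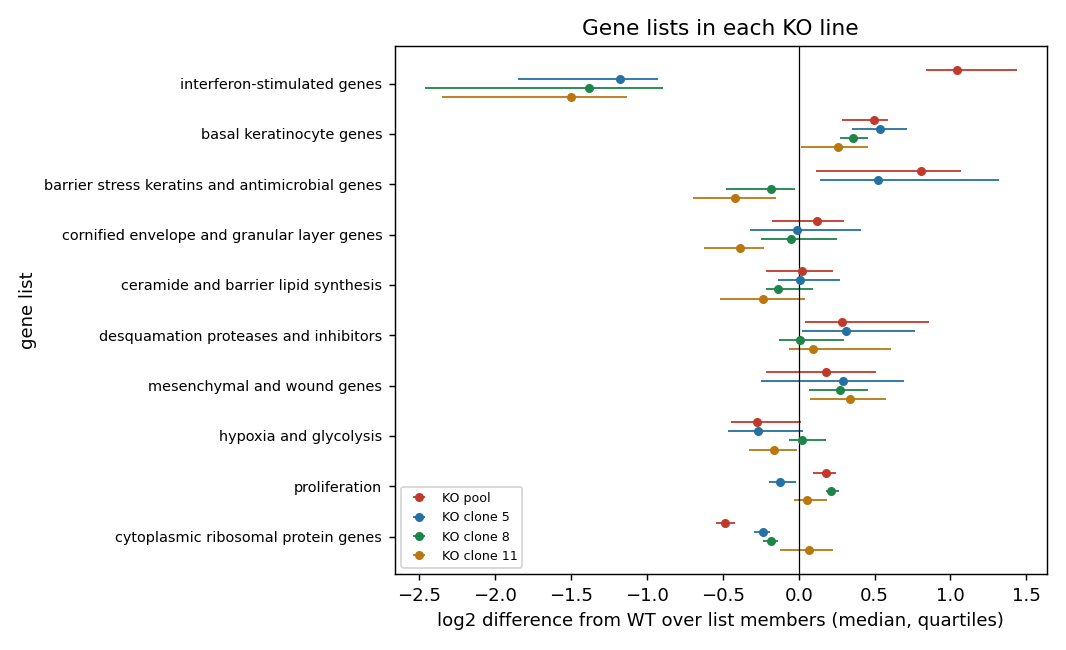
Log2 difference from WT over the members of 10 gene lists (list axis) in each KO line, as the median (point) and quartiles (bar). Interferon-stimulated genes lie at 1.04 in the pool and at -1.18 to -1.50 in the clones, and basal keratinocyte genes at 0.26 to 0.54 in the 4 lines.

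In the KO pool, which can hold cells with different edits, genes of interferon response and of a stressed barrier were higher than in WT. Of 29 interferon-stimulated genes 28 rose (29 adjusted over the list alone), MX2 by 1.90 ± 0.14, BST2 by 1.64 ± 0.10, OAS1 by 1.34 ± 0.11 and HERC6 by 1.24 ± 0.11 among them (adjusted p = 3.19e-27, and 0.114 with an estimated correlation). Among 22 barrier stress keratins and antimicrobial genes 12 rose and 2 fell (13 and 2 adjusted over the list alone), with S100A12 by 2.12 ± 0.27, KRT6B, a keratin with close paralogs, by 1.71 ± 0.13, IL36G by 1.41 ± 0.21 and IL36RN by 0.95 ± 0.11 (adjusted p = 7.83e-06, and 0.392 with an estimated correlation). Basal keratinocyte genes had 12 rises of 20 (14 adjusted over the list alone), desquamation genes 8 of 21 (also 8), proliferation genes 7 of 33 (also 7), with FOXM1 by 0.55 ± 0.10, and replication-dependent histone genes 5 of 8 (also 5). Falls were made by 61 of 77 ribosomal protein genes (71 adjusted over the list alone; median -0.48, and -0.36 after quantile normalisation) and 14 of 30 hypoxia and glycolysis genes (16 adjusted over the list alone). With an estimated correlation the adjusted p of these 6 lists was 0.392 to 0.754. CDKN2B, an inhibitor of cyclin-dependent kinases, went from a normalised count of 3.55 to 2248 (5.25 ± 0.09). Its neighbour MTAP went from 1.18 to 299 (2.85 ± 0.09) and MMP9 from 84.5 to 911 (2.76 ± 0.32). CDKN2B and MTAP were low in clones 8 and 11 too, with CDKN2B at a mean log2 value of 5.69 and 6.55, against 5.95 in WT. The WT counts of MMP9 were uneven, at 187, 30.4 and 36.2 in replicates 1, 2 and 3. The largest falls included HSPB8 (-3.05 ± 0.15), MYH14, a nonmuscle myosin (-2.45 ± 0.13) and CWH43 (-2.32 ± 0.07). SLX1A (3.11) and its copy SLX1B (-3.01) changed in opposite directions and are uncertain, and the first loses the call in a robust fit (adjusted p = 0.0572). In total 1425 genes rose and 1036 fell, 140 and 55 of them by at least 1. The count was 4174 with library weights and 1534 with the stricter filter. The histone list lost its call without KO pool replicate 2 (adjusted p = 0.0947), without WT replicate 1 (0.0685) and with no filter (0.0625).

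In clone 5 the interferon-stimulated genes went the other way. Of 29 measured, 26 fell and 1 rose (the same counts adjusted over the list alone), with falls of IFI27 (-5.00 ± 0.14), IFI6 (-3.80 ± 0.20), BST2 (-3.68 ± 0.10) and IFI44 (-2.32 ± 0.13) (adjusted p = 1.42e-25, and 0.134 with an estimated correlation). Basal keratinocyte genes had 14 rises of 20 (15 adjusted over the list alone), KRT14, a keratin of the basal layer, by 0.89 ± 0.14 and CDH3 by 0.71 ± 0.10 among them, and barrier stress genes 12 rises and 1 fall of 22 (12 and 3 adjusted over the list alone), with S100A12 by 2.38 ± 0.27 and KRT6B by 1.65 ± 0.13. Desquamation genes rose in 8 of 21 (9 up and 1 down adjusted over the list alone), SPINK7 by 1.89 ± 0.15 among them. Mesenchymal and wound genes had 11 rises and 4 falls of 24 (13 and 5 adjusted over the list alone). Hypoxia and glycolysis genes had 15 falls and 2 rises of 30 (16 and 2 adjusted over the list alone), BNIP3 (-1.71 ± 0.12) and EGLN3 (-1.67 ± 0.15) included. Ribosomal protein genes had 14 falls of 77 (none adjusted over the list alone). These 6 lists had an adjusted p of 0.447 to 0.703 with an estimated correlation. CDKN2B reached a normalised count of 2751 (5.53 ± 0.09), MMP9 2414 (4.07 ± 0.32), BGN, a small matrix proteoglycan, 2390.3 (2.98 ± 0.13) and KRT2, a keratin of upper epidermal layers, 22471 (2.96 ± 0.28). CWH43 dropped from 1422 to 7.22 (-4.45 ± 0.07). In total 1598 genes rose and 1239 fell, 159 and 141 of them by at least 1. The count was 4370 with library weights and 1700 with the stricter filter.

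In clone 8 the same list of 29 interferon-stimulated genes had 27 falls (29 adjusted over the list alone), with IFI6 (-3.76 ± 0.23), BST2 (-3.48 ± 0.12), IFI27 (-3.21 ± 0.16) and XAF1 (-2.78 ± 0.14), and this call held with an estimated correlation (adjusted p = 0.0228). Basal keratinocyte genes had 6 rises of 20 (8 adjusted over the list alone), with COL7A1 by 0.61 ± 0.13, and proliferation genes 3 of 33 (also 3), TPX2 by 0.61 ± 0.10, UBE2C by 0.53 ± 0.10 and AURKA by 0.47 ± 0.10. Of 6 measured fibroblast genes 3 rose and 1 fell (4 and 1 adjusted over the list alone). COL5A1, of fibrillar collagen, rose by 1.37 ± 0.11 while DCN, decorin, fell (-0.95 ± 0.16). Mesenchymal and wound genes had 4 rises and 1 fall of 24 (8 and 3 adjusted over the list alone). With an estimated correlation the adjusted p of these 4 lists was 0.156 to 0.758, that of the fibroblast genes was 0.0945 with no filter, and that of the mesenchymal and wound genes was 0.0642 without WT replicate 3 and 0.151 without clone 8 replicate 2. With fry, the proliferation and the mesenchymal and wound lists had an adjusted p of 0.0546 and 0.0764. FOS, an immediate early gene, rose by 2.37 ± 0.37, GSTA1, a glutathione transferase with close paralogs, by 2.05 ± 0.34, FADS2, a fatty acid desaturase, by 1.99 ± 0.13 and MMP9 by 1.99 ± 0.36. METRNL dropped from a normalised count of 2399 to 6.14 (-5.21 ± 0.15). In total 582 genes rose and 577 fell, 44 and 85 of them by at least 1, and the count was 2541 with library weights and 652 with the stricter filter. With 1 of its 2 libraries left out the count was 420 (without replicate 2, where MMP9 missed the threshold at adjusted p = 0.0578) or 500 (without replicate 1), with the lone library assumed to vary like the others.

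In clone 11 genes of the late barrier were lower than in WT. Of 30 cornified envelope and granular layer genes 15 fell and 2 rose (17 and 2 adjusted over the list alone), with CDSN (-1.75 ± 0.17), the corneodesmosin gene, CRNN (-1.61 ± 0.14) and TGM1 (-0.63 ± 0.10), a transglutaminase (adjusted p = 5.28e-05, and 0.585 with an estimated correlation). Of 43 genes of ceramide and barrier lipid synthesis 16 fell and 4 rose (21 and 6 adjusted over the list alone), with ELOVL1 (-1.08 ± 0.12), SDR9C7 (-0.98 ± 0.11) and SMPD3 (-1.16 ± 0.15) against a rise of FADS2 by 1.02 ± 0.11 (adjusted p = 0.00355, 0.0523 with fry and 0.795 with an estimated correlation). Barrier stress genes had 10 falls of 22 (11 adjusted over the list alone), LCN2 (-1.15 ± 0.11) and KRT6B (-1.10 ± 0.13) among them. Of 29 interferon-stimulated genes 27 fell (28 adjusted over the list alone), with IFI27 (-5.28 ± 0.14) and IFI6 (-4.33 ± 0.20) (adjusted p = 2.50e-30, and 0.079 with an estimated correlation). Lysosome genes had 14 falls and 1 rise of 34 (the same counts adjusted over the list alone), and hypoxia genes 9 and 1 of 30 (likewise). Mesenchymal and wound genes had 12 rises and 1 fall of 24 (12 and 2 adjusted over the list alone), and 4 of the 6 fibroblast genes rose (also 4), COL5A1 by 1.56 ± 0.10 and DCN by 0.95 ± 0.15. With an estimated correlation the adjusted p of the barrier stress, lysosome, hypoxia, mesenchymal and fibroblast lists was 0.0871 to 0.585. GSTA1 rose by 4.00 ± 0.30, KRT13, a keratin of mucosal epithelium, by 2.91 ± 0.17, SLCO1A2 by 2.10 ± 0.13 and BGN by 2.05 ± 0.13, and METRNL (-4.84 ± 0.13) dropped to a normalised count of 19. In total 1859 genes rose and 1814 fell, 88 and 159 of them by at least 1. The clone 11 libraries were less alike than those of other lines, and the 13 mitochondrially encoded genes, a sign of RNA quality, were lower beside these lists, 3 past the test and 7 adjusted over the list alone (median -0.75, adjusted p = 0.00717, 0.0691 without replicate 3, 0.141 with fry and 0.795 with an estimated correlation). Without replicate 3 their median was -0.38. The fit of clone 11 and WT alone called 1988 genes, library weights 2156 and the stricter filter 2444. The 6 basal keratinocyte rises of 20 (also 6 adjusted over the list alone; adjusted p = 0.035) lost the call without replicate 1 (adjusted p = 0.371), without WT replicate 2 (0.0872) or 3 (0.0538), with fry (0.0526) and with an estimated correlation (0.795).

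The knockout clones were then compared with one another, in contrasts from which WT cancels. Clone 5 stood above clones 8 and 11 in CDKN2B by 5.35, METRNL by 4.21 and TERT, the catalytic subunit of telomerase, by 3.62, and below them in CWH43 (-4.30), IRX3 (-3.10) and INSYN1 (-2.69). Against the mean of clones 5 and 11, clone 8 was higher in CWH43 (2.11), MYL9 (2.00) and IFI27 (1.93) and lower in CDKN2B (-3.32), METRNL (-2.38) and BGN (-2.08). CWH43 (-0.05, adjusted p = 0.706) and METRNL (-0.37, adjusted p = 0.102) did not differ between clones 8 and 11 past the threshold. CDKN2B differed by -0.86 there, with normalised counts of 0 to 1.57 in clone 8 and 17.8 to 27.2 in clone 11. Such low counts are compressed on the log2 scale, on which the values of these 3 genes come mostly from clone 5. Against the mean of clones 5 and 8, clone 11 was higher in DCN (2.68), GSTA1 (2.49) and KRT13 (2.39) and lower in TERT (-3.11), SPRR1A, a cornified envelope precursor (-2.40), and SLC16A6 (-2.07). Barrier stress genes were higher in clone 5 than in clone 11 in 19 of 22 and lower in 0 (20 higher adjusted over the list alone; median 1.03, adjusted p = 7.07e-10, and 0.526 with an estimated correlation), and cornified envelope genes higher in 15 and lower in 1 of 30 (the same counts adjusted over the list alone; adjusted p = 1.08e-04, and 0.526 with an estimated correlation). Proliferation genes were lower in clone 5 than in clone 8 in 12 of 33 (23 adjusted over the list alone; adjusted p = 1.89e-10, and 0.295 with an estimated correlation). Clones 5 and 11 differed in 4256 genes, 2211 higher and 2045 lower in clone 5, clones 8 and 11 in 1840 (905 and 935) and clones 5 and 8 in 1446 (834 and 612). The second of these was 281 from the 5 libraries alone, 496 and 606 without clone 8 replicate 2 or 1, 987 and 1166 without clone 11 replicate 2 or 3 and 4230 without clone 11 replicate 1. Clones 5 and 11 alone gave 2642, and clones 5 and 8 gave 693 and 775 without clone 8 replicate 2 or 1 and 756 with the stricter filter. Library weights gave 2536, 1050 and 2877 for these pairs in the order of their counts.

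Against the mean of the 3 clones, the KO pool was higher in interferon-stimulated genes, while its differences in barrier genes depended on the clone. All 29 interferon-stimulated genes were higher (29 adjusted over the list alone), with a median of 2.49 and the largest differences in BST2 by 5.28 ± 0.09, a restriction factor of enveloped viruses, IFI27 by 5.08 ± 0.12 and IFI6 by 5.00 ± 0.17. This call held with an estimated correlation (adjusted p = 0.00398). Barrier stress genes were higher in 13 of 22 (16 adjusted over the list alone), with KRT6B by 1.71 ± 0.11 and DEFB103A, which has a near-identical copy, at 0.98, and cornified envelope genes in 8 of 30 (15 higher and 1 lower adjusted over the list alone), TGM1 by 0.69 ± 0.08 among them. The barrier stress score was 0.657 in the pool, 0.647 in clone 5, -0.209 in clone 8 and -0.436 in clone 11, so the pool did not stand apart from clone 5. The cornified envelope score was 0.0952 in the pool, 0.00795 in clone 5, -0.0523 in clone 8 and -0.447 in clone 11. Members of the small proline-rich family, of the cornified envelope, were higher in 3 of 9 (4 adjusted over the list alone), SPRR1A by 1.25 ± 0.12 (mean log2 level 12.78 in the pool, 12.32 in clone 5, 12.33 in clone 8 and 9.93 in clone 11). The family score was 0.347 in the pool, -0.275 in clone 5, 0.114 in clone 8 and -0.45 in clone 11. Ribosomal protein genes were lower in 48 of 77 (65 adjusted over the list alone; median -0.36, and -0.31 after quantile normalisation). With an estimated correlation these 4 lists had an adjusted p of 0.202 to 0.601. GSTA1 was lower in the pool (-2.74 ± 0.25), as were ITIH5 (-2.39 ± 0.08) and DHRSX (-2.04), a gene with an identical copy under another identifier that is uncertain. In total 980 genes were higher and 712 lower, 102 and 16 of them by at least 1. The count was 849 or 956 without pool replicate 2 or 3, 2820 without clone 11 replicate 1, 2935 with library weights and 1007 with the stricter filter. With all clone libraries taken as 1 group, a 2-group fit gave 146. There were 56 genes that rose in the pool and fell in all 3 clones against WT and 1 that did the reverse.

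**Figure D5:**
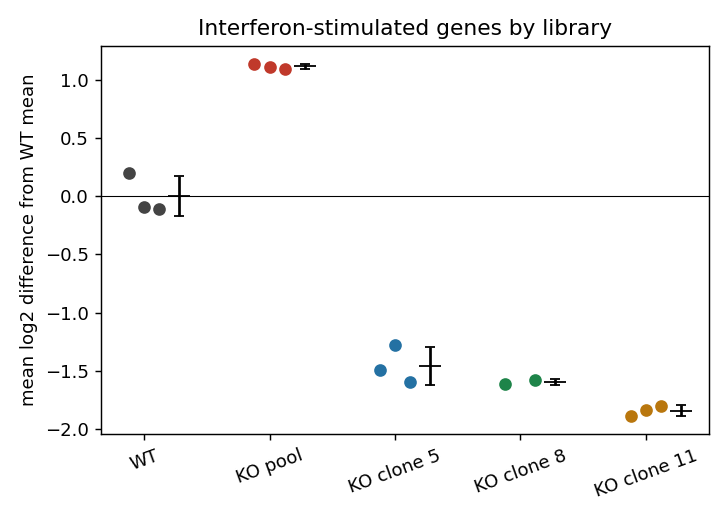
Mean log2 difference of 29 interferon-stimulated genes from the WT mean in each library (points), with the mean and SD of each line (bars). The 3 pool libraries lie at 1.10 to 1.14, and the 8 clone libraries between -1.89 and -1.28, all below the lowest WT library at -0.11.

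Each line was last set against the mean of the other 4 to see whether WT stood furthest from the rest. Clone 11 differed in 4903 genes (2468 higher, 2435 lower), WT in 2642, clone 5 in 2019 (1165 and 854), the pool in 1836 (1064 and 772) and clone 8, with 2 libraries, in 748 (313 and 435). Of the 5736 genes changed against WT in at least 1 KO line, 3025 passed in exactly 1. Leaving out a library moved WT to 1653 (without WT replicate 3) or 1749 (without WT replicate 1), the pool to 936 (without pool replicate 2), 1096 (without pool replicate 3) or 2799 (without clone 11 replicate 1) and clone 5 to 1192 (without its replicate 1) or 1265 (without its replicate 3). Clone 8 moved to 199 (without its replicate 2), 244 (without its replicate 1) or 1333 (without clone 11 replicate 1), and clone 11 to 3245 (without its replicate 2). With library weights, which did not converge, the order turned, with 3728 genes for WT, 3313 for the pool, 3103 for clone 5, 2011 for clone 11 and 1586 for clone 8. With the other lines taken as 1 group, 2-group fits gave 3203 for clone 11, 867 for WT, 134 for the pool and 117 for clone 5.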

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

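The tests of interferon-stimulated genes, of the genes on 9p21 and 17q, and of the share of short-arm genes and the copy number of chromosome 20 were chosen only after the result was seen, as were the limit of 0.25 on list differences (with adjusted p under 0.05 in camera and fry) and the rule for genes under the filter. The differences between knockout lines below were each tested as a contrast of lines, from which WT cancels.

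Interferon-stimulated genes were higher in the KO pool and lower in the 3 clones than in WT, with a median of 2.49 between pool and clones. The smaller gap between the ranges of the libraries, in the mean log2 score of the list, was 0.89, so a single deviating library is argued against. After quantile normalisation the median was 2.48, which argues against the scaling of the deposited values as the cause. A candidate explanation is the level of IFNK, a type I interferon of keratinocytes, whose normalised count was 72.7 in the pool, 13.9 in WT, 0.692 in clone 5, 1.40 in clone 8 and 0.393 in clone 11, with a smaller gap between ranges of 0.44 in log2 value. Its level could as well follow from the interferon response, and the pool having been kept as a mixed culture, the cloning and the edit itself remain open and untested.

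Genes of the short arm of chromosome 20 were lower and those of its long arm higher in all 4 KO lines than in WT. Of the 103 tested short-arm genes 96.1% lay below 0 in the mean of the lines, which argues against a few strongly changed genes, and after quantile normalisation their median was -0.40, which argues against scaling. The lowest median of 10000 random gene sets matched on expression was -0.083, which argues against expression level, and of 264 windows of 10 Mb the 3 with a median below every window of the other chromosomes (lowest -0.18) lay on this short arm and its border. A copy-number difference of chromosome 20 between the WT line and the KO lines may underlie the pattern, but the count of KO libraries with a short-arm median below 0 and a long-arm median above 0, 11 of 11, restates the pattern and lends it no support. It stays open, since DNA was not analysed here, as does an effect of the edit, and MMP9 and SGK2 lie on the long arm.

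MIR31HG, MTAP, CDKN2A and CDKN2B, near one another on 9p21 (chromosome 9, 21455642 to 22009363), were expressed in the KO pool and clone 5 and near the lowest value elsewhere, and B3GNTL1, which is low in WT, and METRNL, adjacent at the end of 17q (chromosome 17, 82942155 to 83095119), lay near the lowest value in clones 8 and 11. The number of libraries on the other side of the midpoint from their line was 0. This argues against a library swapped between WT, the pair of pool and clone 5, and the pair of clones 8 and 11. A swap within either pair would not show in these genes. The flanking 9p21 genes differed by 0.45 at most, against 1.56 for the smallest difference in the block, which argues against scaling or depth. In clones 8 and 11 the largest difference of a block gene from WT was 0.61, against 1.64 for the smallest in the pool and clone 5, so for the 9p21 genes a knockout effect alike in every line is argued against. That 0.61 was CDKN2B in clone 11, at normalised counts of 17.8 to 27.2 against 1.59 to 4.96 in WT. CDKN2B was thus low in clone 11 but above WT. A difference in DNA between cells of different ancestry within the line could give such blocks, and it was not tested.

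Further differences between lines were as follows. Genes past the threshold numbered 1446 between clones 5 and 8, 4256 between clones 5 and 11, 1840 between clones 8 and 11 and 1692 between the pool and the mean of the clones. The log2 difference of CACFD1 was 0.78 between clones 5 and 11, 0.50 between clones 8 and 11 and -0.42 between the pool and the clones. Between clones 5 and 8 the list medians were 0.55 for barrier stress genes, -0.33 for proliferation, -0.27 for hypoxia and glycolysis, 0.35 for mucosal keratinocyte genes and -0.41 for fibroblast genes. Between clones 5 and 11 they were 0.38 for basal, 0.27 for spinous and 0.43 for cornified envelope genes, 0.28 for ceramide synthesis, 1.03 for barrier stress genes, 0.28 for interferon-stimulated genes, 0.43 for hair follicle and sebaceous genes and -0.29 for ribosomal protein genes. Between the pool and the clones they were 0.28 for cornified envelope genes, 0.38 for the small proline-rich family, 0.68 for barrier stress genes and -0.36 for ribosomal protein genes. With an estimated correlation the adjusted p of these lists was 0.203 to 0.305 between clones 5 and 8, 0.526 to 0.553 between clones 5 and 11 and 0.202 to 0.601 between the pool and the clones.

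Clone 5 differed from the mean of clones 8 and 11 in CDKN2B (5.35), METRNL (4.21), TERT (3.62), CWH43 (-4.30), IRX3 (-3.10) and INSYN1 (-2.69). Clone 8 differed from the mean of clones 5 and 11 in CWH43 (2.11), MYL9 (2.00), IFI27 (1.93), CDKN2B (-3.32), METRNL (-2.38) and BGN (-2.08). Clone 11 differed from the mean of clones 5 and 8 in DCN (2.68), GSTA1 (2.49), KRT13 (2.39), TERT (-3.11), SPRR1A (-2.40) and SLC16A6 (-2.07). The pool differed from the clones in BST2 (5.28), IFI27 (5.08), IFI6 (5.00), GSTA1 (-2.74), ITIH5 (-2.39) and DHRSX (-2.04).

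Some protein-coding genes left out by the filter had a signal in every library of a KO line at least 1 above the highest WT library. In the pool these were GPC4 (1.22 above the WT mean on the log2 scale), CPPED1 (1.79), NLGN4X (1.70), CDKN2A (1.67) and COL22A1 (1.41). In clone 5 they were CPPED1 (2.24), CDKN2A (1.64), OTOP3 (1.26) and RSC1A1 (1.24), in clone 8 IGF2BP1 (2.08), and in clone 11 ITGA9 (1.37), FGF17 (1.38), IGF2BP1 (2.14) and FAM25C (2.27).

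Other splits of the libraries were fitted as 2 groups. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each such comparison 1 split, the real one, gave as many genes. The real value was 2768 for the pool and WT (highest other 2), 3239 for clone 5 and WT (highest other 1), 1988 for clone 11 and WT (highest other 0) and 2642 for clones 5 and 11 (highest other 1). For the larger comparisons 100 splits were drawn, and in each the share that gave as many genes as the real split was under 0.05. These splits take libraries as exchangeable, whereas libraries of a line correlate (0.453 in the random-block fit), so a chance division of whole lines is not excluded, and with 5 lines and 1 WT line it cannot be. All KO libraries against WT gave 867 genes, a number reached by 2 of 100 splits, and the clones against WT gave 741, reached by 2 of 100. The pool against the clones gave 146, the pool against all other lines 134 and clone 5 against all others 117, each reached by 3 of 100. The highest of the other splits, with 3203, 1955, 3800, 3203 and 3203 genes in that order, set the 3 clone 11 libraries apart, which points to a structure of the samples by line. Clone 11 against all others gave 3203, reached by 1 of 100 (highest other 882). Genes changed the same way in all 4 lines numbered 393, reached by 1 of 100 labellings (highest other 0). A shuffled labelling mixes libraries of different lines in a group, which raises the spread. Few genes could then pass in all 4 contrasts, so no conclusion is drawn from that 0. Clone 8 has 2 libraries, so no splits were counted for it.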

How the results depend on the processing

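The values without chromosome 20 and on the log2 of a normalised count plus 1 were chosen only after the result was seen. Counts of genes below are for the KO pool, clone 5, clone 8, clone 11, the mean of 4 KO lines and the mean of 3 clones against WT, in that order where all are given, then for pairs of clones, the pool against the clones, a line against the other 4 and the same way in all 4 lines. No filter, quantile normalisation, median centring, no trend and a robust fit kept every count within 1.5 times the reported one, as did the replicate block, which gave 2307, 2669, 949, 3484, 2453 and 2346. Replicate numbers did not pair the libraries: 5 of 26 same-number pairs correlated above 0.1 and 2 of 14 libraries correlated best with their own number, so the replicate block is given only as a check. With the stricter filter, which tests fewer genes, counts were 1534, 1700, 652, 2444, 1613 and 1536, then 756 (clones 5 and 8), 1007 (pool and clones), 1110, 1155 and 340 (pool, clone 5 and clone 8 against the other 4) and 243 (all 4 lines). Differences of at least 1 numbered 195, 300, 129, 247, 111 and 136, then 199, 307 and 111 (clones 5 and 8, 5 and 11, 8 and 11), 118 (pool and clones), 109, 129, 63 and 160 (each line against the other 4) and 19 (all 4 lines), since a further condition is set. With library weights they were 4174 (pool), 4370 (clone 5), 2541 (clone 8) and 2156 (clone 11), then 2877, 2536 and 1050 for the pairs, 2935 for the pool and clones and 3313, 3103, 1586 and 2011 against the other 4. The weights stopped before they converged and gave clone 11 replicate 2 a weight of 0.0019, against up to 3.74 elsewhere. Only the 2 groups compared gave 1988 (clone 11), 2642 (clones 5 and 11) and 281 (clones 8 and 11), with fewer libraries in the fit. The mean of 4 KO lines gave 867 in the 2-group fit and 89 with the line as random block, where 1191 genes had an unadjusted p under 0.05 and libraries of a line correlated at 0.453. Without chromosome 20 it gave 2409, with 309 in all 4 lines, and on the log2 of a normalised count plus 1 it gave 2631 and 393.

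With each library left out in turn the counts were 1736 to 3194, 2065 to 3549, 420 to 1735, 2518 to 5226, 1653 to 3433 and 1638 to 3430, then 693 to 1931, 3098 to 5813 and 496 to 4230 for the pairs, 849 to 2820 for the pool and clones, 936 to 2799, 1192 to 2962, 199 to 1333 and 3245 to 6126 against the other 4 and 192 to 477 in all 4 lines. Each highest count came without clone 11 replicate 1, and where clone 8 was left with 1 library it was assumed to vary like the other lines. The target gene, at -0.32 in the mean of the lines, lay at -0.37 to -0.25 (adjusted p from 0.00823 to 0.239), and it passed the threshold with quantile normalisation (-0.35), median centring (-0.34) and library weights (-0.24). Of the 7 lists called for the mean of the lines 0 passed with an estimated correlation, and 7 to 10 were called with a library left out. Among genes and lists named singly none reversed. In alternatives other than leaving out a library 13 gene results and 66 list results no longer passed and 830 and 179 stayed unchanged. With a library left out 1 and 19 no longer passed and 1119 and 667 stayed unchanged. Unchanged gene results include those that passed in neither fit, since CACFD1 in clones 5 and 8 was counted and was not called. Where a cause is not given it was not tested. In simulated data 62.7% of changes of 0.5 were recovered for clone 8 and 82.1% for clone 5, so small changes could be missed, and since depth was not varied, what it limits was not measured.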

Other observations

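Several signalling lists were called in clone 5 or in clone 8. In clone 5, p53 target genes had 8 falls of 26 (8 falls and 1 rise adjusted over the list alone), with GDF15 (-0.97 ± 0.11), a stress cytokine, and CDKN1A (-0.49 ± 0.07), a cell cycle inhibitor (limma and camera, list adjusted p = 0.0461, and 0.639 with an estimated correlation). Notch pathway genes had 6 falls and 2 rises of 19 (the same counts adjusted over the list alone), with HEYL (-0.97 ± 0.13), NRARP (-0.57 ± 0.09) and the ligand JAG1 (-0.77 ± 0.13) (list adjusted p = 0.0407, and 0.682 with an estimated correlation). The mean log2 difference of the Notch list from WT was -0.23 in clone 5, -0.16 in the pool, -0.14 in clone 11 and -0.06 in clone 8. Lower values were thus not confined to clone 5. In clone 8, 5 of 22 genes of NRF2 and oxidative stress fell (6 adjusted over the list alone), with SRXN1 (-0.73 ± 0.10), and AKR1C2, which has close paralogs, at -0.70 ± 0.10 (list adjusted p = 0.0296, and 0.741 with an estimated correlation). After quantile normalisation these lists had an adjusted p of 0.0539, 0.062 and 0.151. The p53 list missed the threshold without WT replicate 1 (0.0606), without clone 5 replicate 3 (0.128) and with the replicate block (0.057). The Notch list missed it without WT replicate 3 (0.0761), clone 5 replicate 1 (0.0667) and replicate 3 (0.0968). The NRF2 list missed it without WT replicate 2 (0.108). Without clone 8 replicate 1, which leaves 1 library of that clone, its call was not kept either, at a median of -0.13. Ribosomal protein genes in clone 8 had 1 fall of 77 (none adjusted over the list alone; median -0.18, adjusted p = 4.78e-06, 0.0631 after quantile normalisation, 0.272 with fry and 0.853 with an estimated correlation).

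Some genes of the calcium and endocytosis lists changed in the mean of the KO lines although the lists were not called. CALML3, a calmodulin-like protein, rose by 0.96 ± 0.17, while ATP2C2, a calcium pump of the secretory pathway (-0.89 ± 0.10), and the calcium-binding S100A11 (-0.52 ± 0.11) fell. TFRC, the transferrin receptor, fell (-0.63 ± 0.08), as did EPN3, an epsin (-0.60 ± 0.08), and DNM1, a dynamin, rose by 0.38 ± 0.06. Among 23 spinous keratinocyte genes 5 rose and 5 fell (5 and 7 adjusted over the list alone; list adjusted p = 0.797), with KRT2 at 2.05 ± 0.23 and KLF4, a transcription factor of differentiation, at -0.71 ± 0.08. TERT, which the construct that made the cells immortal supplies, had a normalised count of 836 ± 205 (SD, n = 3) in WT, 2524 ± 796 (SD, n = 3) in the pool, 2115 ± 534 (SD, n = 3) in clone 5, 236 ± 35.2 (SD, n = 2) in clone 8 and 25.6 ± 8.19 (SD, n = 3) in clone 11, and which copy the reads came from is not known.

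The lists called in the mean of the KO lines did not include cornified envelope, ceramide and barrier lipid or barrier stress genes. Nor did they include proliferation, p53, Notch, NRF2, mitochondrially encoded or histone genes, whose rises and falls in that mean are not given here. Further lists not called there had these numbers of rises and falls. Late cornified envelope genes had 0 and 4 of 16, the small proline-rich family 1 and 1 of 9, cholesterol synthesis 1 and 3 of 24, lamellar body genes 3 and 3 of 27, tight junctions 2 and 3 of 16, desmosomes and adherens junctions 3 and 2 of 19, cytokines and chemokines 0 and 1 of 10, the unfolded protein response 3 and 3 of 24, immediate early and heat shock genes 4 and 2 of 22, aryl hydrocarbon receptor targets 1 and 1 of 6 and simple epithelial keratins 2 and 1 of 6. Cell type lists had 6 and 3 of 12 for mucosal keratinocytes, 4 and 1 of 10 for hair follicle and sebaceous genes, 3 and 1 of 6 for fibroblasts, 0 and 0 of 2 for melanocytes, 0 and 0 of 2 for Langerhans and immune cells and 3 and 1 of 5 for endothelial and Merkel cells. The pool against the clones also had calls for desquamation (2 higher of 21, 5 adjusted over the list alone), proliferation (3 of 33, also 3 adjusted over the list alone) and replication-dependent histone genes (3 of 8, 4 adjusted over the list alone), with an adjusted p of 0.702, 0.612 and 0.601 with an estimated correlation. With fry the desquamation and proliferation lists had an adjusted p of 0.242 and 0.121. The desquamation call was lost without pool replicate 2 (adjusted p = 0.134), pool replicate 3 (0.170) and clone 11 replicate 1 (0.106), and the histone call without pool replicate 2 (0.0759) and with no filter (0.227). The mean log2 score of the mitochondrially encoded genes, as a difference from the WT mean, had an SD of 0.14 in WT, 0.43 in the pool, 0.43 in clone 5, 0.01 in clone 8 and 0.51 in clone 11.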
